A study of Mus musculus with 2 samples.

How the data were processed

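Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was carried out on 2 mouse cell populations sorted from pancreatic adenocarcinoma. Both populations were positive for EpCAM, an epithelial surface protein, and were separated by REM2, known from the study as a reporter of Musashi-2 (Msi2), an RNA-binding protein. Reporter-positive cells are called stem and reporter-negative cells non-stem in the labels. Per the labels' protocols, cells were fixed in 1% formalin, chromatin was sheared to 200 to 400 bp, and 75-nt single-end reads were planned at 20 M per sample. The labels state 70000 cells. Each group had 1 library, so no difference below has a replicate check and no p-value was computed.

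The authors deposited 1 list of enriched regions (islands) per library, so islands were called per sample and not on pooled reads. Per the submitters' processing notes, the tools were FastQC, Trim Galore, Bowtie2 2.1.0, SAMtools 0.1.16, Picard 1.98 and SICER, on build mm10. SICER joins enriched windows across short gaps into islands and suits broad histone marks. Its window, gap, threshold and the use of an input control are not given in the sources used here. Each deposited list has 3 columns, chromosome, start and end, and holds no read count, height, fold, score or p-value per island. In both lists every start was a multiple of 200 and every end lay 199 bp above one, so positions count from 0 with both ends included. Widths were taken as multiples of 200 bp accordingly, and the smallest gap between islands was 400 bp in both lists. Coordinates are printed counting from 1. No island passed the mm10 end of its chromosome. The sequencing depth of each library is unknown from the lists. The number and width of islands depend on depth and on enrichment, so a difference in either can add or remove islands.

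Gene positions came from a RefSeq gene table of assembly GRCm38.p6, whose primary chromosomes are those of mm10. It held 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table gives each gene's start and end but no strand and no exons. The planned measures centred on the transcription start site, plus or minus 1 kb for promoters and 25 kb for covered length, could therefore not be computed. In their place, a gene was called marked where an island lay within 1 kb of either of its ends, which includes 3′ ends. Covered length was the length of islands inside the gene body extended by 5 kb on either side, which had been planned as an alternative. A stretch inside 2 overlapping genes counts for both. Positions within exons, introns or UTRs were not analysed here.

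Overlap of islands was counted with bedtools 2.31.1, with a minimum of 1 bp, and covered base pairs were compared on the 200-bp grid of the lists. Chance overlap was taken from 20 sets of islands shifted along their chromosomes by at least 5 Mb. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals. They cover counting error only, and neighbouring islands and genes are not independent. All other computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Islands within 12.5 kb were joined into stitched domains, and the 500 domains with the most covered base pairs were taken from each list. These are not called super-enhancers, because no signal was available to rank them.

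Before the data were examined, 18 gene lists were fixed, covering 269 genes, all of which were found in the table: immune, fibroblast, endothelial, acinar, endocrine and ductal epithelial markers, sort and reporter genes, stem and progenitor genes, epithelial-mesenchymal transition (EMT), nuclear receptors, developmental signalling, cytokine signalling, cell cycle, adhesion and matrix, lipid metabolism, classical and basal tumour subtypes, and housekeeping genes. A list's median difference in covered length, stem minus non-stem, was placed among 10000 random gene lists of the same size, matched in 20 bins on the mean covered length of both libraries, with genes without any island in a bin of their own. The percentile describes these 2 libraries and is not a test of the conditions. Lists below the 2.5th or above the 97.5th percentile are said to lie outside the range of the random lists. Because the non-stem list covers more of the genome, every direction was also examined after multiplying non-stem covered length by the genome-wide ratio of the lists, here called scaling.

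The genes named were chosen by rules fixed in advance for measures around transcription starts. The rules were applied to gene ends and extended gene bodies instead, so the rankings used were not those planned. Taken were the 10 genes with the largest gain and the 10 with the largest loss of covered length. Their bodies lie at least 50 kb apart, a spacing planned between transcription starts. Also taken were the 5 per direction marked at an end in one list only by the widest islands. In each gene list, the members marked at an end in one list only and the 2 with the largest difference were named. The sort genes were named in any case. Results for some genes that these rules select are not reported here. Predicted genes named only by a Gm number or a Rik code were skipped. Others are said to have been chosen after their values were seen. Alternatives tried were other overlap minimums, the widest 50% of each list, lists trimmed to equal length, other distances around genes and other stitching distances. Ranking by island score was planned and not run, since the lists hold none. The gene-level script was tested on simulated data in which the islands of 100 genes were removed from one copy of the non-stem list and those of 100 others from the other copy. All 100 and all 100 were found in the right class and direction. Since the copies were otherwise identical, this checks the script only and not its accuracy on lists that differ in depth or width. Of 200 random lists of 15 genes drawn from the measured values, 3 lay outside the percentile limits.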

Results

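The data consist of 2 lists of H3K27ac islands, 1 from reporter-positive (stem) and 1 from reporter-negative (non-stem) EpCAM-positive cells of mouse pancreatic adenocarcinoma. The comparison asks where the active chromatin of stem cells differs from that of non-stem cells. There are no replicates, the depth of each library is unknown from the lists, and every difference below is between these 2 libraries. The stem list held 69440 islands covering 116.65 Mb, or 4.28% of the genome. The non-stem list held 68278 islands covering 159.94 Mb, or 5.87%. The numbers of islands were thus close, while the stem islands covered 0.729 times the length of the non-stem islands (log2 ratio −0.46). Median island width was 1.2 kb in the stem list (quartiles 0.8 and 2.0 kb) and 1.6 kb in the non-stem list (quartiles 1.2 and 2.8 kb). Islands of at most 800 bp made up 34.0% of the stem list (95% exact interval 33.6 to 34.3%) and 14.97% of the non-stem list (14.7 to 15.2%). Islands wider than 8 kb numbered 537 in the stem and 1628 in the non-stem list. Neither list held an island on chromosome Y.

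**Figure D1:**
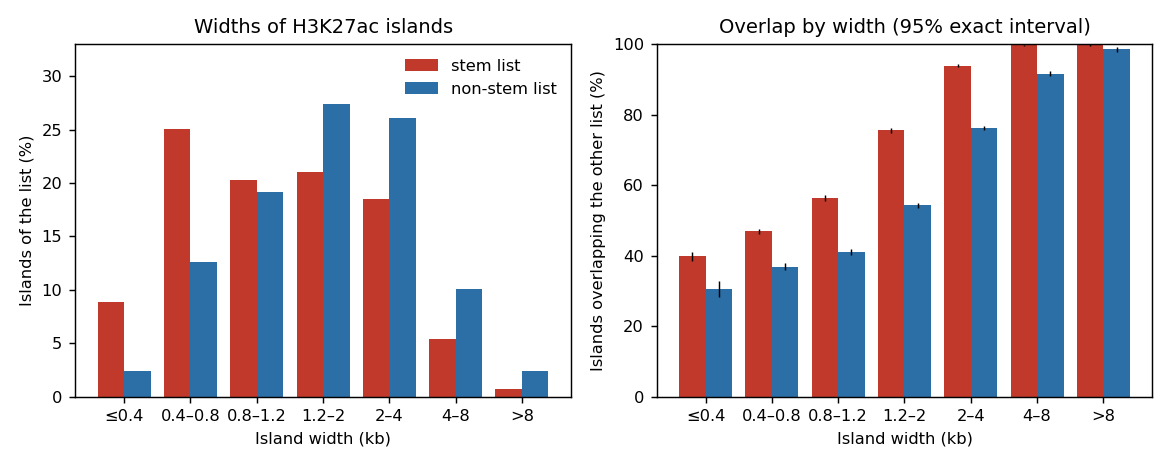
Share of each list's islands by width in kb (left) and share of islands in each width class that overlap the other list, in percent with exact 95% intervals (right); red bars are the stem list and blue bars the non-stem list. Islands of 0.4 to 0.8 kb make up 25.1% of the stem and 12.6% of the non-stem list, and overlap rises with width in both lists.

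Most islands were found in both populations. Of the stem islands, 45936 (66.2%, 95% exact interval 65.8 to 66.5%) overlapped a non-stem island, and of the non-stem islands 40651 (59.5%, 59.2 to 59.9%) overlapped a stem island. Shifted islands overlapped in 9.51% and 9.04% of cases. The overlap followed width, from 39.8% of stem islands up to 400 bp to 99.6% of those of 4 to 8 kb. In the non-stem list it went from 30.6% to 91.6% over the same classes. By length, 79.7 Mb was covered in both lists, 36.96 Mb in the stem list alone and 80.2 Mb in the non-stem list alone, so that 40.5% of all covered base pairs were shared. Islands without overlap lay near gene ends less often than overlapping islands, but they were also narrower. Of unmatched stem islands, 6.19% (5.89 to 6.51%) lay within 1 kb of a protein-coding gene end, against 27.4% of overlapping stem islands (26.98 to 27.8%). The non-stem values were 6.37% (6.08 to 6.66%) and 30.5% (30.1 to 31.0%). Median widths of unmatched and overlapping islands were 0.8 and 1.6 kb in the stem list and 1.2 and 2.2 kb in the non-stem list. A wider island reaches a gene end more easily, and width was not matched here. Unmatched islands of at most 800 bp lay near a gene end more often than shifted ones (stem 5.83% against 3.95%, non-stem 5.75% against 3.92%). Within genes but away from their ends lay 52.4% of unmatched stem and 54.1% of unmatched non-stem islands. The overlap depends on its definition, since a reciprocal overlap of 50% was met by 35.2% of stem and 35.8% of non-stem islands.

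Marking at gene ends was largely shared. Of 21887 protein-coding genes, 12739 (58.2%, 57.5 to 58.9%) had an island within 1 kb of an end in both lists, 667 (3.05%, 2.82 to 3.28%) in the stem list only and 878 (4.01%, 3.76 to 4.28%) in the non-stem list only. Shifted islands, here 1 shifted set per list and so without a spread, marked 14.6% of genes in the stem list and 17.3% in the non-stem list. The widest islands at stem-only ends lay at Tns2, which encodes the focal-adhesion protein tensin-2 (9.2 kb), Fscn3 (9.0 kb), Xpo7, a nuclear export receptor (7.4 kb), Serinc2 (6.2 kb) and Adig (5.6 kb). The islands at Fscn3, Xpo7 and Adig lay wholly outside the annotated gene, within 1 kb of an end, so they may belong to neighbouring sequence. Non-stem islands were not absent around these 5 genes. At Xpo7, for example, islands covered 13.5 kb of the extended gene in the non-stem and 14.3 kb in the stem list, and within 25 kb of Tns2 and of Xpo7 the non-stem list had more covered length. The widest at non-stem-only ends lay at Cmklr1, a chemerin receptor of macrophages (32.4 kb), Ankrd44 (21.0 kb), Tg (20.8 kb), F7, coagulation factor VII (18.0 kb) and Pkd1l2 (17.6 kb). Cmklr1 had 36.2 kb of islands in the non-stem list and none in the stem list. The Tg gene spans Sla, which encodes an adaptor protein of leukocytes.

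The 10 genes with the largest gain in kb of H3K27ac covered length in stem cells began with Magi1 and Mecom. Gene length was not adjusted for, so ranks in kb favour long genes and do not order relative change. Magi1, a scaffold of tight junctions (chromosome 6, 93675453 to 94283929), had 86.2 kb of islands in the stem list and 26.2 kb in the non-stem list. Mecom, a zinc-finger transcription factor (chromosome 3, 29951296 to 30509759), had 86.2 kb and 29.4 kb. Msi2 itself (chromosome 11, 88339382 to 88718306), whose reporter defined the sort and which is therefore no independent finding, had 97.2 kb and 55.4 kb. The others were Shroom3, an actin regulator of epithelial shape (89.8 and 48.0 kb), Wwc1, a Hippo pathway protein (54.0 and 19 kb), Zbtb7c (47.8 and 15.2 kb), Sh3rf1 (63.8 and 31.8 kb), Auts2 (45.6 and 15.6 kb), Etl4 (53.0 and 23.6 kb) and Cftr (30.8 and 3.2 kb). Cftr encodes the chloride channel of ductal cells. Msi1, the paralogue of Msi2, had no island at either end, with 2.4 kb in the stem and 3.2 kb in the non-stem list, an order that turned after scaling and after trimming the longer list. Epcam, positive in both sorts, had 7.4 and 5.6 kb.

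The 10 genes with the largest loss in stem cells, that is with most excess in the non-stem list, included Lpp and Trps1. They were also ranked in kb without regard to gene length, and Lpp, the largest loss, kept 0.49 times its non-stem covered length. Trps1, a GATA-type repressor (chromosome 15, 50654757 to 50890631), had 9.0 kb in the stem and 99.0 kb in the non-stem list. Lpp (chromosome 16, 24393350 to 24992578) had 104.8 and 214.2 kb, and Creb5 (chromosome 6, 53287226 to 53700364) 24.2 and 110.2 kb. Runx1, a transcription factor of blood development, had 63.3 and 127.9 kb. Bach2, a repressor best known in lymphocytes, had 40.0 and 104.3 kb, and Prkch, protein kinase C eta, 24.4 and 103.2 kb. The remaining 4 were Asap1 (56.2 and 133.2 kb), Tg (37.2 and 108.5 kb), Med12l (28.2 and 97.8 kb) and Snx29 (37.4 and 103.1 kb). All 10 kept this direction after scaling. A stitched domain inside Med12l, named after its values were seen, held 91.2 kb of non-stem and 23.2 kb of stem islands. It also overlaps Gpr171, P2ry12, P2ry13 and P2ry14, so the difference cannot be assigned to Med12l alone. Over all genes, 5065 had more covered length in the stem list and 10373 in the non-stem list, a share of 32.8% for stem. After scaling the numbers were 9598 and 6417, a share of 59.9%, so a small difference at a single gene has no fixed direction.

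**Figure D2:**
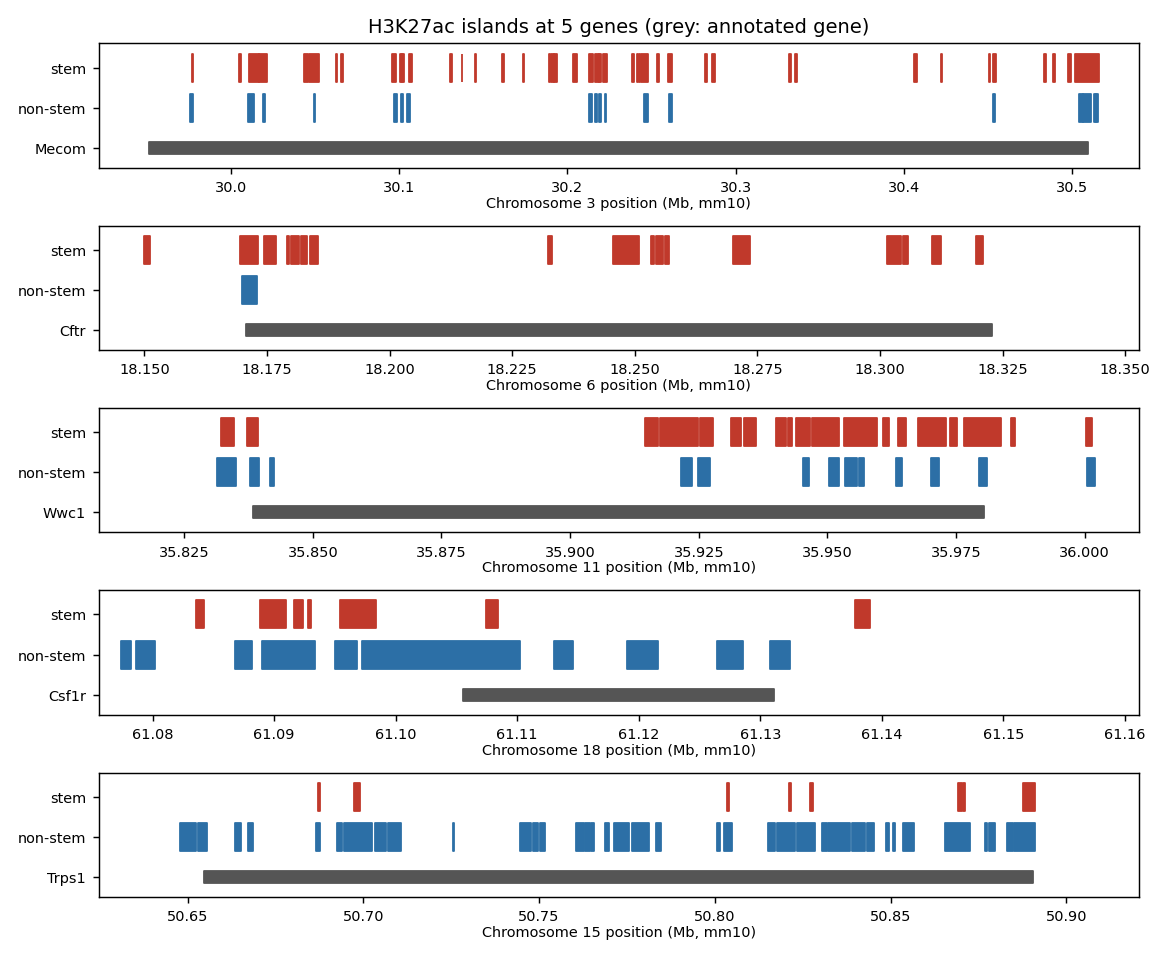
Islands of the stem list (red) and the non-stem list (blue) along Mecom, Cftr, Wwc1, Csf1r and Trps1 with 30 kb on either side; the x axis is the mm10 position in Mb and grey bars are the annotated genes. Mecom, Cftr and Wwc1 have more covered length in the stem list, while Trps1 has 99.0 kb of non-stem and 9.0 kb of stem islands.

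Genes of pancreatic ductal epithelium had more covered length in the stem list, while leukocyte markers had more in the non-stem list. The purity of the sorts is unknown. A smaller epithelial share in the non-stem sort therefore cannot be told apart from a difference between epithelial cells, for the ductal and classical genes alike. The 16 immune marker genes had a median difference of −4.9 kb, with 15 lower in the stem list. Of the 16 ductal epithelial genes, 15 had more covered length in the stem list, and all 16 were marked at an end in both lists. The count was also 15 after scaling, which lowers only the non-stem side and so could not have reduced it. The median difference was 2.5 kb, above all 10000 matched random lists. Cftr was among the genes with the largest differences. The keratin genes Krt19 (12.7 kb in stem and 8.1 kb in non-stem cells) and Krt8 (16.4 and 10.2 kb) and the epithelial transcription factor Grhl2 (18.6 and 11.2 kb) also had more in stem cells, and Spp1 had less (4.6 and 7.3 kb). These 4 genes, Gata6, Pdx1, Wnt4, Wnt7a, Wnt7b and the genes named for having no island in either list were chosen after their values were seen. All 12 genes of the classical tumour subtype had more covered length in the stem list, with a median difference of 2.9 kb, again above all random lists and opposite in direction to the immune markers. The trefoil factor genes Tff1 (9.5 and 4.1 kb) and Tff2 (7.0 and 0.6 kb) differed most, and Tff2 and Agr2 (8.2 and 3.0 kb) were marked at an end in the stem list only. The pancreatic transcription factor genes Gata6 (9.4 and 6.4 kb) and Pdx1 (11.2 and 8.4 kb) belonged to the same list. Of 10 basal subtype genes, 5 had more in stem cells, 1 less and 4 none in either. Their median difference was 0.3 kb (99.2nd percentile), which fell inside the range of the random lists after scaling (97.0th). Dsg3, a desmosomal cadherin (3.6 and 0 kb), was marked in the stem list only, and Ly6d had 7.4 and 2.8 kb.

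Stem and signalling genes were more mixed. Of 19 stem and progenitor genes, 11 had more covered length in the stem list, 5 had less and 3 had none in either. The median difference was 0.4 kb (99.8th percentile), but the mean was −0.09 kb, and the list lay inside the random range after scaling (92.8th). Hmga2, an oncofetal chromatin protein (13.4 and 6.2 kb), and Cd44, an adhesion receptor (41.9 and 62.3 kb), differed most and in opposite directions. Aldh1a7 was marked in the stem list only (0.6 and 0 kb). Lgr5 was marked at an end in the non-stem list only, although its covered length was 2.2 kb in stem and 1.8 kb in non-stem cells. Sox2, Nanog and Lin28b had no island in either list. Among 25 developmental signalling genes, 15 had more in the stem list, 9 less and 1 none, with a median difference of 1.0 kb, above all random lists, and a mean of −0.47 kb. The Wnt ligand genes Wnt7b (39.4 and 18.0 kb), Wnt7a (22.2 and 6.0 kb) and Wnt4 (11.4 and 6.0 kb) had more, whereas Tcf7l2, a transcription factor of Wnt signalling (34.0 and 68.4 kb), and Notch2 (42.0 and 75.0 kb) had less. Lef1 was marked at an end in the non-stem list only, with 3.2 kb in stem and 3.4 kb in non-stem cells, an order that turned after scaling and trimming.

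Of 20 nuclear receptor genes, 8 had more in the stem list and 12 less, with a median difference of −0.48 kb (96.4th percentile). After scaling the direction turned, with 16 more and 4 less and a median of 2.69 kb. Rxra had 22.8 kb in stem and 55.4 kb in non-stem cells. Ppard had 30.4 and 40.0 kb, an order that turned after scaling, and Nr2f1 (0 and 1.2 kb) was marked in the non-stem list only. The adhesion and matrix list had 9 genes with more and 9 with less in stem cells, a median difference of 0.4 kb (99.5th percentile) and a mean of −0.61 kb, and lay inside the random range after scaling (88.8th), with 13 more and 5 less and a median of 2.08 kb. Itga2, an integrin subunit that binds collagen, had 33 and 22 kb. Cd47 (17.0 and 31.9 kb) and Lama3 (8.0 and 11.0 kb), whose order turned when the longer list was trimmed, were marked at an end in the non-stem list only.

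Immune genes had less covered length in the stem list, although both lists held islands at markers of leukocytes despite the EpCAM sort of both populations. Of 16 immune marker genes, 12 were marked at an end in both lists, 3 in the non-stem list only and 1 in neither, and their covered length summed to 102.0 kb in the stem and 254.0 kb in the non-stem list. None of the 16 had more covered length in the stem list, 15 had less and Cd3e had none in either. After scaling 13 had less and 2 had more. The median difference was −4.9 kb (0.27th percentile). Ptprc, the pan-leukocyte marker CD45, had 19.4 kb in stem and 49.6 kb in non-stem cells, and Ikzf1, a lymphoid transcription factor, had 25.4 and 50.1 kb. The myeloid genes Csf1r (chromosome 18, 61105572 to 61131139; 1.0 and 17.6 kb), Itgam (4.2 and 22.0 kb) and Adgre1 (0 and 4.4 kb) were marked at an end in the non-stem list only. Cytokine signalling genes showed a similar lean, with 20 of 25 lower in the stem list and a median difference of −3.6 kb (percentile 2.315, and 3.8 after scaling, when 13 were lower and 12 higher). Il10ra, the interleukin-10 receptor of leukocytes, had 3.0 and 17.5 kb and Lifr 6.6 and 18.8 kb. Ccl2 (0 and 8.5 kb) and Lifr were marked in the non-stem list only. Il33 was marked at an end in the stem list only, with 4.8 and 7.4 kb. The same leaning of leukocyte markers towards the non-stem list applies beside each gene group described here.

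Of 10 endothelial genes, 2 had more and 7 less in the stem list, with a median difference of −2.1 kb (1.36th percentile; 22.3rd with a gene window of 25 kb). Pecam1 (21.6 and 42.5 kb), Vwf (7.7 and 24.0 kb), Erg (0 and 11.8 kb) and Eng (3.8 and 9.2 kb) were marked in the non-stem list only. Pecam1 and Eng are also known in myeloid cells. Fibroblast genes had little in either list. Of 12, 1 had more and 6 less in stem cells and 5, among them Col3a1, Col1a2 and Dcn, had none in either, with a median difference of −0.3 kb (3.34th percentile). Pdgfrb (2.9 and 11.1 kb) and Pdgfra (1.4 and 4.6 kb, turned when the longer list was trimmed) differed most, and Pdgfra was marked in the non-stem list only. Of 13 EMT genes, 4 had more and 9 less in stem cells, with a median difference of −1.57 kb (14.6th percentile). Zeb2, an EMT transcription factor that is also expressed in leukocytes, had 17.6 and 69.4 kb, Fn1, fibronectin, had 5.4 and 18.2 kb, and Twist1 (0 and 1.2 kb) was marked in the non-stem list only.

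Other pancreatic lineages were sparsely marked. Among 13 acinar genes, 5 had more and 2 less in stem cells and 6, including the digestive enzyme genes Cpa1, Prss2 and Pnlip, had none, with a median of 0 kb (51.3rd percentile). Nr5a2, an acinar transcription factor (9.8 and 0.8 kb), and Cela1 (5.4 and 12.6 kb) differed most. Gata4 (20.1 and 13.5 kb), Cel (3.4 and 0.8 kb, an order that turned with a gene window of 25 kb) and Ctrb1 (0.4 and 0 kb) were marked in the stem list only. Of 13 endocrine genes 8, including both insulin genes, had none in either list, 3 had more and 2 less, with a median of 0 kb (50th percentile). Nkx6-1 and Nkx2-2 (each 1.4 and 0 kb) were marked in the stem list only, and Mafa had 2.2 and 0.8 kb. Cell cycle genes had 6 more, 7 less and 2 equal (median 0 kb, 89.7th percentile), and after scaling 10 more and 5 less (median 1.03 kb). The largest differences were at Mki67 (5.8 and 17.8 kb) and Mcm4 (2.2 and 5.2 kb). Lipid metabolism genes had 7 more and 8 less (median −0.6 kb, 82.7th percentile), and after scaling 10 more and 5 less (median 1.252 kb). The largest differences were at Lpin2 (28.9 and 40.5 kb) and Cpt1a (27.8 and 36.4 kb, turned after scaling). Housekeeping genes served as a reference, with 3 more and 11 less and a median of −1.6 kb, at the 43.4th percentile, which became 0.79 kb after scaling, with 12 more and 2 less. B2m (6.2 and 12.48 kb) and Rplp0 (8.7 and 4.4 kb) differed most. The 3 sort and reporter genes had a median difference of 1.8 kb (96.6th percentile).

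**Figure D3:**
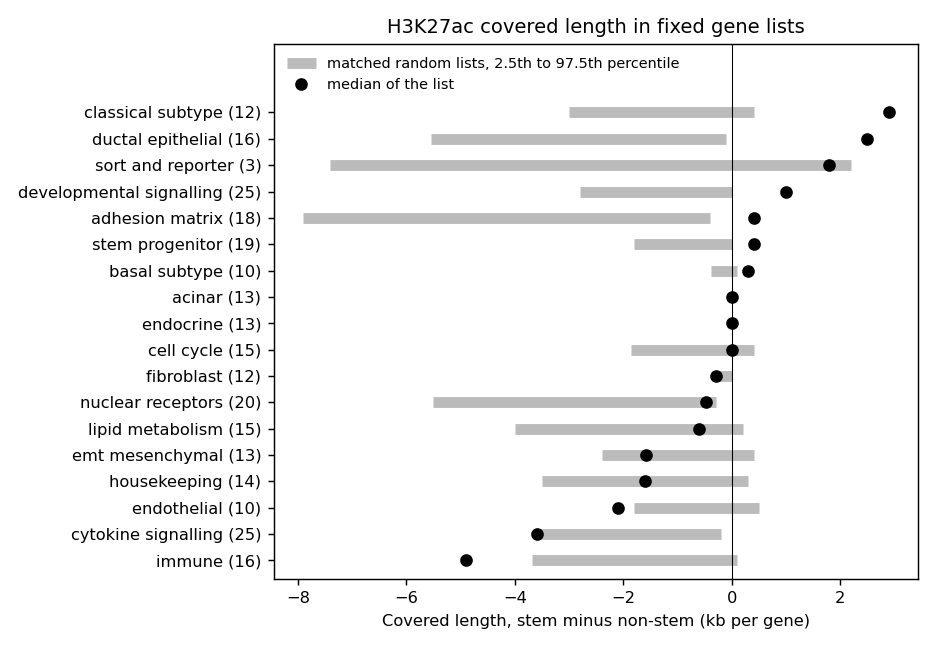
Median difference in covered length per gene, stem minus non-stem in kb (black points), of the 18 fixed lists, with the number of genes in brackets; grey bars span the central 95% of 10000 matched random lists. The classical subtype (2.9 kb) and ductal epithelial (2.5 kb) lists lie right of their bars and the immune list (−4.9 kb) lies left of its bar.

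Large stitched domains were partly shared. Of the 500 stem domains with most covered length, 269 (53.8%, 49.3 to 58.2%) overlapped one of the 500 of the non-stem list, and 231 did not. Of 500 non-stem domains, 266 overlapped and 234 did not. The 500th domain covered 30.2 kb in the stem and 47.2 kb in the non-stem list, and 89 of the 231 unmatched stem domains had at least as much covered length in the non-stem list, against 0 of the 234 in the other direction. The longest domains were shared. The longest stem domain, at Cebpb and Ptpn1 on chromosome 2 (167588401 to 168011400), held 202.2 kb of stem and 300.4 kb of non-stem islands. The longest non-stem domain, at Irf2bp2 on chromosome 8 (126472001 to 126946800), held 345.2 and 205.0 kb. The loci and genes named in this paragraph were chosen after their values were seen. Of the ductal epithelial genes, 6 lay in unmatched stem domains (among them Krt19, Krt7, Cdh1, Muc1 and Elf3) and 0 in unmatched non-stem domains. Because the 500th domain is shorter in the stem list, an unmatched stem domain need not hold more stem islands. The Muc1 domain held 42.6 kb of stem and 46.4 kb of non-stem islands, and those at Cdh1 (39.4 and 38.2 kb) and Krt7 (40.6 and 37.6 kb) were close, against 33.6 and 18.8 kb at Krt19. Classical subtype genes gave 3 (Tff1, Tff2 and Pdx1) and 0. Immune genes gave 1 (Cd52, with 46.8 kb of stem and 51.4 kb of non-stem islands) and 3 (Ptprc, Itgam and Ikzf1), and cytokine signalling genes 2 (Il34 and Il17re) and 5 (Il10rb, Il10ra, Csf1, Lif and Il4ra). Msi2 lay in an unmatched stem domain.

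The ratio of covered length was not even along the genome. Chromosome 13 had the lowest stem to non-stem ratio, 0.586 (2716 stem and 3176 non-stem islands), and 20 of its 24 bins of 5 Mb lay below the genome-wide 0.729. Chromosome 6 had the highest, 0.821 (4317 and 3793 islands), with 5 of 28 bins below. The other chromosomes lay between 0.668 for chromosome 16 and 0.789 for chromosome 4.

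**Figure D4:**
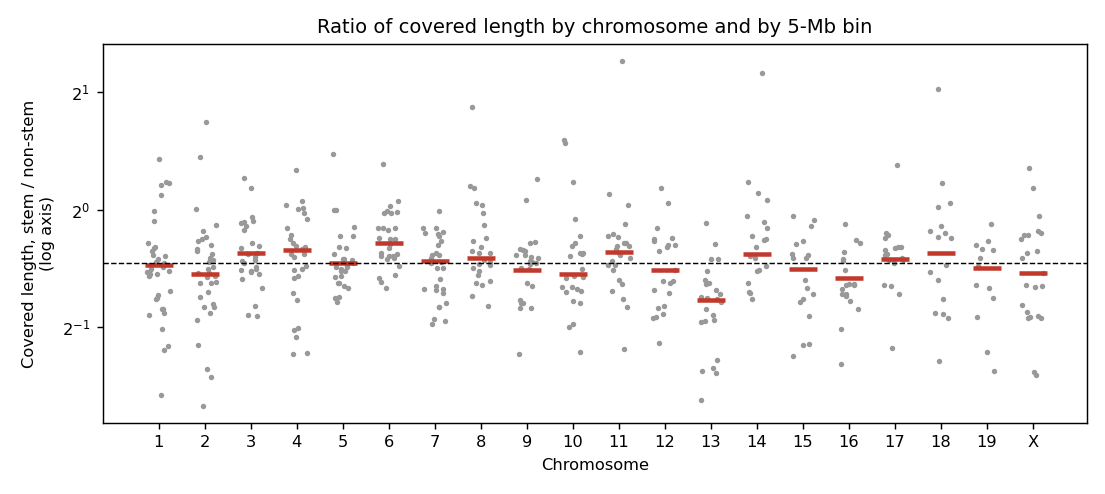
Ratio of covered length, stem over non-stem, on a log axis, for each chromosome (red bars) and its bins of 5 Mb with at least 20 kb of non-stem islands (grey points); the dashed line is the genome-wide ratio of 0.729. Chromosome 13 lies lowest at 0.586 and chromosome 6 highest at 0.821.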

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

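The overlap of islands moved most with its definition. When 50% of an island had to be covered, 60.6% of stem and 46.3% of non-stem islands qualified, and a reciprocal 50% gave 35.2% and 35.8%. The widest 50% of a list against the whole other list gave 84.0% and 76.8%. Islands of at least 1 kb, an alternative chosen after seeing the data, gave 73.3% and 54.3%. Trimming the longer list to equal numbers gave 66.7% for stem islands. The share of covered base pairs in both lists was 39.5% with the widest 50% of each list and 38.8% with the non-stem list trimmed to the stem length. Genes marked at an end in the stem list only numbered 1240 with the widest 50% of islands, above the non-stem count of 1004 at that setting. Genes with more covered length in the stem list numbered 8249 after trimming and 9598 after scaling, and those with more in the non-stem list 6872 and 6417, so the majority turned under both. Scaling and the wider gene window were chosen after seeing the data. Of 99 single genes examined, 10 turned direction under at least 1 of 3 settings, for causes that were not tested. Stem minus non-stem covered length was −1.4 kb at Tns2, −5.0 kb at Xpo7 and −1.2 kb at Cel with 25 kb on either side. It was 1.4 kb at Pdgfra, 0.6 kb at Cd47, 3.2 kb at Lama3, 0.8 kb at Lef1 and 2.4 kb at Msi1 after trimming, and 1.23 kb at Ppard, 1.252 kb at Cpt1a, 0.72 kb at Lef1 and 0.066 kb at Msi1 after scaling. The ductal epithelial, developmental signalling and classical subtype lists lay above, and the immune list below, the range of random lists under the wider window, the widest 50% and scaling. Over these settings and the main one, 4 to 6 lists lay above and 2 to 3 below the range. The share of long stem domains that matched moved by less than its interval with 5-kb stitching (50.8%) and with 250 domains (50.4%). Ranking by summed island score was not run, since the lists hold no score. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. Depth is unknown, so islands near the calling limit in either library cannot be separated from missing signal.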

Other observations

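The immune and fibroblast marker counts were fixed before the data were examined, while the other tests in this part were chosen after the pattern they concern had been seen. Loci in this paragraph and genes named in the next were chosen after their values were seen. Several long non-stem domains without a match among the long stem domains lay at clusters of immune genes. A domain over the chemokine genes Ccl3, Ccl4, Ccl5, Ccl6 and Ccl9 on chromosome 11 held 103.2 kb of non-stem and 22.8 kb of stem islands. A domain over the Fc receptor genes Fcgr2b, Fcgr3 and Fcgr4 on chromosome 1 held 101.6 and 24.4 kb. A domain at Cd274 and Pdcd1lg2, the genes of the checkpoint ligands PD-L1 and PD-L2, held 117.0 and 38.6 kb. On the stem side, a domain at Elf3, an epithelial transcription factor, held 59.6 kb of stem and 43.0 kb of non-stem islands, and one within Wwc1 held 51.4 and 14.8 kb.

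Leukocyte marker genes carried islands in both lists, with more covered length in the non-stem list, and the kind of leukocyte was examined with added lists. The macrophage list includes Fcgr3, which lies in the Fc receptor domain chosen after its values were seen. Of 20 macrophage genes, 0 had more covered length in the stem list and 19 had less, with a median difference of −9.7 kb, below all 10000 matched random lists. At an end, 10 were marked in both lists and 8 in the non-stem list only. Among them Cd86 had 6.6 kb in stem and 34.4 kb in non-stem cells, Cx3cr1 1.0 and 19.01 kb, Cybb 0.6 and 15.8 kb, and Lyz2, among the most abundant macrophage transcripts, 0 and 4.2 kb. All 10 neutrophil genes with any island had less in the stem list (median over 12 genes −5.22 kb), including Fpr1 (0 and 13.5 kb). T-cell genes (median −1.03 kb, 19.7th percentile) and B-cell genes (median −1.92 kb, 5.46th percentile) lay inside the range of random lists, and 7 genes of each list were marked at an end in both libraries.

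A candidate explanation is that the non-stem sort held macrophages or other myeloid cells, although both sorts selected EpCAM-positive cells. The purity of the sorts is unknown from the lists. With such cells present, ductal and classical genes could also have less covered length in the non-stem list, which was not tested. This explanation required at least 80% of macrophage genes with an island to lie below the genome-wide ratio. Of 20 such genes 90% did, but the 95% exact interval (68.3 to 98.8%) reaches below 80%. All 10 neutrophil genes with an island also lay below the ratio, so the share does not single out macrophages. The macrophage list was added after the immune genes had been seen. Acetylation in reporter-negative epithelial cells could give the same share, which therefore cannot decide between the 2. The count fixed beforehand was less clear: 3 of 16 immune genes were marked at an end in the non-stem list only, between the 5 set for immune cells and the 2 set against them. The share was 58.3% of 12 T-cell genes (27.7 to 84.8%) and 45.5% of 11 B-cell genes (16.7 to 76.6%). Of 12 fibroblast genes, 1 was marked in the non-stem list only. These values met the limits set against T cells, B cells and fibroblasts, but the intervals are too wide to decide. It remains open, as untested, whether reporter-negative epithelial cells carry this acetylation themselves, and islands at Ptprc (19.4 kb) in the stem list show that leukocyte genes were not free of islands there either.

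The non-stem list covered more of the genome with fewer islands, and lower sensitivity of the stem library alone would make its islands a subset of the non-stem islands. Of 45835 stem islands of at least 1 kb, 23.0% (95% exact interval 22.6 to 23.4%) lay wholly outside non-stem islands. The limits set were 5% for that explanation and 10% against it. The stem islands were thus not a subset of the non-stem islands. Without replicates, the share left unmatched between libraries of the same cells is unknown, so the limits cannot exclude lower sensitivity. The excess of short stem islands may be background calls. Stem islands of at most 800 bp without a non-stem match lay near a gene end 1.47 times as often as shifted islands (5.83% against 3.95%), between the bounds set beforehand, and the non-stem list gave the same 1.47 (5.75% against 3.92%). Background calls therefore stay open, as do depth, enrichment and a more mixed non-stem population.

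The low ratio on chromosome 13 and the high ratio on chromosome 6 could reflect a difference in copy number between the sorted tumour cells. Among genes marked at an end in both lists, chromosome 13 ranked 1 of 20 from the lowest in the median log2 island width ratio (−0.35, SE over genes 0.043) and chromosome 6 ranked 20 (−0.14, SE 0.040). These widths are part of the covered length that singled out both chromosomes, so the ranks largely restate the pattern and do not bear on its cause. Copy number, regional regulation and the presence of other cell types in one sort stay open.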
